A study of Pseudomonas aeruginosa with 5 samples.

How the data were processed

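Total RNA from *P. aeruginosa* PAO1 grown with azithromycin was measured on 5 Affymetrix arrays, 2 without the drug, 1 at 0.5 µg/ml and 2 at 2 µg/ml. Per the labels' protocols, an overnight culture was diluted into 15 ml of LB medium, RNA was preserved with RNAprotect, purified with RNeasy columns and treated with DNase, and biotin-labelled cRNA was hybridized. The deposited values are intensities on a linear scale, 1 signal per probe set, which the authors computed with MAS5 (per the submitters' processing notes). The MAS5 version and its target level are not given in the sources used here. The 2% trimmed mean of every array was checked and lay at 100.2, so the arrays had been scaled to a common level before they were deposited. No column was unused. Groups were taken from the labels, and the number that follows the word replicate in this text only orders the arrays of a group. The labels of 2 arrays, 1 untreated and 1 at 2 µg/ml, hold the word replicate. These are replicate 2 of their groups and are called the second set of arrays. The other arrays, with the one at 0.5 µg/ml, are the first set, so comparisons with 0.5 µg/ml are not balanced between the sets.

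The table holds 5896 probe sets: 5545 for PAO1 genes, 199 for intergenic regions, 117 for other strains or other sequences, 21 for tRNA or rRNA and 14 control probe sets. The PAO1 genes were tested, and the other kinds were left out of the main test and looked at apart. Gene symbols came by locus tag from the RefSeq gene table of assembly ASM676v1, which held 5504 of the tags. There 1737 had a symbol other than the tag, 2 symbols came from the probe set name, and the other genes are named by tag, with PA2019 and PA2018 also given their common names. The files name no genome build, so no position is printed. The table's order of genes and its coding lengths, matched by locus tag, were used only for neighbours and for the trend with length. PA0442 is listed at 0 on all arrays. Some probe sets, 96 with a suffix that marks shared or mixed probes, may bind more than 1 gene.

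Signals were analysed as log2(signal + 8.2), where 8.2 is the 10th percentile of all PAO1 signals. Linear models with 3 groups were fitted to all 5 arrays with limma 3.58.1 (lmFit, contrasts and eBayes, R 4.3.3), with 2 residual degrees of freedom per gene and 6.90 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the 5545 genes within each of 3 comparisons, with a threshold of 0.05. The single array at 0.5 µg/ml is assumed to vary like the other groups. Folds are 2 to the power of the log2 change, errors of log2 changes are standard errors from the moderated variance, and errors of signals are standard deviations. The 29 gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. They were tested again with camera's correlation estimated from the residuals, and with fry. Within each list the genes were also adjusted over the list alone. The gene lists, the comparisons, the test, the threshold and the alternatives except the removal of the length trend were fixed before the data were examined.

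Genes were named by a rule fixed at the same time: up to 12 genes with the largest changes in each direction and comparison, 11 genes of quorum sensing, efflux and methionine metabolism named in every comparison, and up to 4 members of each list by smallest p. The exceptions, chosen after their values were seen, are *hcnA*, *hcnB*, *atpB*, *atpI*, *atpH*, *nuoA*, *fliA*, *mexB*, *oxyR*, *pslA* and *tufA* at 2 µg/ml, PA3287 between the concentrations, and the neighbouring genes of the closing section. Agreement between the concentrations was measured by the correlation of the log2 changes and by shared calls. It was set against 100 simulations of groups without change that share the untreated arrays. The test was tested on simulated data with the spread of these arrays. At 2 µg/ml against untreated it recovered 54% of log2 changes of 1 and 100% of changes of 2, with 3 false calls among the unchanged of the 5545 genes. At 0.5 µg/ml it recovered 15% and 98%, with 4 false calls. Only 100 genes had each size of change, far fewer than passed in the data. Fewer changed genes make the adjustment stricter, so these shares do not measure the power in the data. Of 2 simulated shifted lists, camera with the preset correlation recovered 2 and with the estimated correlation 0. The simulated genes were drawn independently of each other, while the estimated correlation in the data reached 0.479 (TCA cycle list). This simulation therefore cannot show that the preset correlation suits the real lists.

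The alternatives were pseudocounts at the 1st and 25th percentile, quantile normalization, median centring, leaving out the dimmest 25% of probe sets, testing all probe sets but the controls, eBayes with an intensity trend, robust eBayes, a term for the set of arrays, leaving out each array of a replicated group, fitting the untreated and 2 µg/ml arrays alone, and camera with the estimated correlation. With an array at 2 µg/ml left out, the spread comes from the untreated arrays alone, as 1 common value for all genes. The comparison of the concentrations then sets 1 array against 1. Removal of each array's smooth trend with coding length (lowess) was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.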

Results

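*Pseudomonas aeruginosa* strain PAO1, an opportunistic pathogen and the most widely used laboratory strain of its species, was grown in shaken LB medium at 37 °C with azithromycin (AZM). The drug is a macrolide that binds the ribosome. It was present at 0, 0.5 or 2 µg/ml, which the labels give as 1/256 and 1/64 of the minimal inhibitory concentration for the lower and the higher level. Cells were collected 9 h after the drug was added, and total RNA was measured on 5 Affymetrix arrays. There were 2 untreated arrays, 1 array at 0.5 µg/ml and 2 arrays at 2 µg/ml. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and the array at 0.5 µg/ml has no replicate.

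Of 5896 probe sets, 5545 stood for PAO1 genes and were tested. Their median signal was 47.2 and 44.5 on the untreated arrays, 41.9 at 0.5 µg/ml, and 38.7 and 36.7 at 2 µg/ml. The probe sets for genes of other strains gave the background: the 95th percentile of their signals over all arrays was 10.56, and between 82.6% and 89.8% of the PAO1 probe sets on an array lay above it. Across genes, which are not independent replicates, the log2 signals of the untreated arrays correlated with r = 0.965 and those of the arrays at 2 µg/ml with r = 0.974. The array at 0.5 µg/ml correlated with the arrays at 2 µg/ml at 0.961 and 0.943 and with the untreated arrays at 0.85 and 0.855. The untreated arrays and those at 2 µg/ml correlated least, at 0.748 to 0.788.

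The first comparison asked which transcripts differ after growth with 2 µg/ml AZM. The largest rise was that of *mexC* (PA4599), which encodes the periplasmic subunit of the MexCD-OprJ multidrug efflux pump. Its signal was 1373 ± 427 (SD, n = 2) with the drug and 22.7 ± 2.83 (SD, n = 2) without it. That is 43.7-fold higher. PA2019, known as *mexX* and part of the MexXY pump that exports macrolides and aminoglycosides, was 21.1-fold higher (772 ± 82.4 against 30.1 ± 14.6). The largest fall was that of *aprA* (PA1249), which encodes the secreted alkaline protease, from 604 ± 84.6 to 1.8 on both treated arrays. That is under the background level. The staphylolytic protease gene *lasA* (PA1871) fell 56.2-fold (60.9 ± 7.78 against 3947 ± 1136), and *rmf*, which encodes the ribosome modulation factor of stationary-phase cells, fell 32-fold (128 ± 28.5 against 4339 ± 676).

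In all, 2310 of the 5545 genes (41.7%) passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 957 of them higher and 1353 lower with the drug. Changes of at least 2-fold were found in 681 of the higher and 953 of the lower genes, and changes of at least 4-fold in 168 and 276. The arrays of both groups did not overlap for 70% of all genes, where chance gives 33.3%. The median log2 change of all genes was −0.17. Centring each array on its median turned the split to 1239 higher and 1003 lower genes, and quantile normalization to 1150 and 1089. All folds are on the scale of log2(signal + 8.2), which understates the change of dim genes.

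The direction went with the length of the coding sequence. Among the longest 20% of genes, 83 rose and 398 fell at 2 µg/ml, and among the shortest 20%, 258 rose and 225 fell. The rank correlation of length with the log2 change was −0.202 across genes. The second array of a group differed from the first in the same direction, with −0.149 among untreated and −0.186 among treated arrays. With each array's trend with length removed, an alternative chosen after the data were seen, 2215 genes passed, 1104 higher and 1111 lower.

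Most of the other genes among the 12 largest rises have no symbol in the gene table. An exception, *moaB1*, whose product takes part in molybdopterin synthesis, rose to 643 ± 22.6 from a mean of 8.75 (adjusted p = 8.56e-06). As that mean is under the background level of 10.56, the size and rank of its log2 change (5.28 ± 0.25 SE) depend on the pseudocount. PA2712 rose by a log2 change of 4.41 ± 0.25, PA3277 by 4.02 ± 0.27, and PA3386 by 4.01 ± 0.23. PA4963 rose by 3.91 ± 0.24, PA4574 by 3.72 ± 0.24, PA4059 by 3.66 ± 0.27 and PA5357 by 3.62 ± 0.26. The magnesium transport ATPase gene *mgtA* rose by 3.62 ± 0.26 and *trpG*, which encodes a subunit of anthranilate synthase, by 3.69 ± 0.25. Among the 12 largest falls were PA0586 and PA0587, with log2 changes of −5.38 ± 0.25 and −4.73 ± 0.27. PA3416 and PA3415, which the gene table does not name, were at −4.93 ± 0.29 and −4.33 ± 0.25. *nuoG* of NADH dehydrogenase I fell with −4.21 ± 0.25, and PA0049, PA1874, PA2146 and PA2366 fell with changes between −4.51 and −4.19. The means of PA3416 (5.5), PA0587 (9.2) and PA2366 (7.4) with the drug were under the background level, and so the sizes of these falls depend on the pseudocount too, like that of *aprA*. The adjusted p of these 24 genes lay between 8.42e-06 and 2.87e-05.

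The genes known to be controlled by quorum sensing, the cell-density signalling of this species, moved apart from the genes that make and sense the signals. Of 24 measured genes for quorum-sensing regulated exoproducts, 18 fell and 2 rose, the same counts as when adjusted over the list alone. Their median log2 change was −1.89 (camera with a preset correlation, adjusted p = 1.85e-05; adjusted p = 0.417 with an estimated correlation). Besides *aprA* and *lasA*, the chitinase gene *chiC* fell with a log2 change of −2.95 ± 0.23, and PA2939 with −3.26 ± 0.27. The elastase gene *lasB* fell 3.84-fold (914 ± 26 against 3540 ± 197, adjusted p = 0.000248), and the rhamnolipid gene *rhlA* 1.79-fold (adjusted p = 0.0175). The *rhlA* call was lost under median centring and without any 1 of the untreated or 2 µg/ml arrays (adjusted p from 0.0066 to 0.0974 over the alternatives, 0.0974 without replicate 1 at 2 µg/ml, 0.0535 without replicate 2, and 0.06 and 0.0644 without untreated replicates 1 and 2). The 2 that rose were *hcnA* and *hcnB* of hydrogen cyanide synthase, with log2 changes of 1.33 ± 0.26 and 0.90 ± 0.23. The call of *hcnB* was lost without untreated replicate 1 (adjusted p = 0.0668) and without replicate 2 at 2 µg/ml (0.0658), over a range of 0.00317 to 0.0668.

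Of 17 genes for the synthesis and sensing of acyl-homoserine lactones and of the quinolone signal PQS, 1 rose, 3 fell and 13 did not pass, the same counts as when adjusted over the list alone (median 0.03, camera adjusted p = 0.761). The log2 change was −0.49 ± 0.24 for *lasI* (adjusted p = 0.137) and 0.22 ± 0.28 for *lasR* (adjusted p = 0.561). It was 0.48 ± 0.26 for *rhlI* (adjusted p = 0.165) and 0.37 ± 0.23 for the PQS receptor gene *mvfR* (*pqsR*, adjusted p = 0.237). For *rhlR* it was 0.72 ± 0.26 (adjusted p = 0.0517), which passed under 7 alternatives, median centring and leaving out replicate 1 at 2 µg/ml (adjusted p = 0.0387) among them, with a range of 0.015 to 0.324. In the operon for PQS synthesis *pqsA* rose (1.21 ± 0.23), while *pqsB* and *pqsC* fell (−1.13 ± 0.24 and −1.40 ± 0.28), as did *pqsL* (−1.02 ± 0.25). The call of *pqsL* was lost without untreated replicate 1 (adjusted p = 0.0644) and without replicate 1 at 2 µg/ml (0.0709), over a range of 0.00554 to 0.0709. Of 10 measured phenazine genes, 6 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose (camera adjusted p = 0.0953, range 0.0254 to 0.243, past the threshold under quantile normalization alone). The gene that rose over all genes was *phzM* (476 ± 64.6 against 71.5 ± 1.84), which encodes a modifying enzyme of pyocyanin synthesis. Most phenazine probe sets could also bind the near-identical copy of the operon, so *phzE2* (−1.94 ± 0.23) and *phzB1* (−1.72 ± 0.24) stay uncertain as to the copy.

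**Figure D1:**
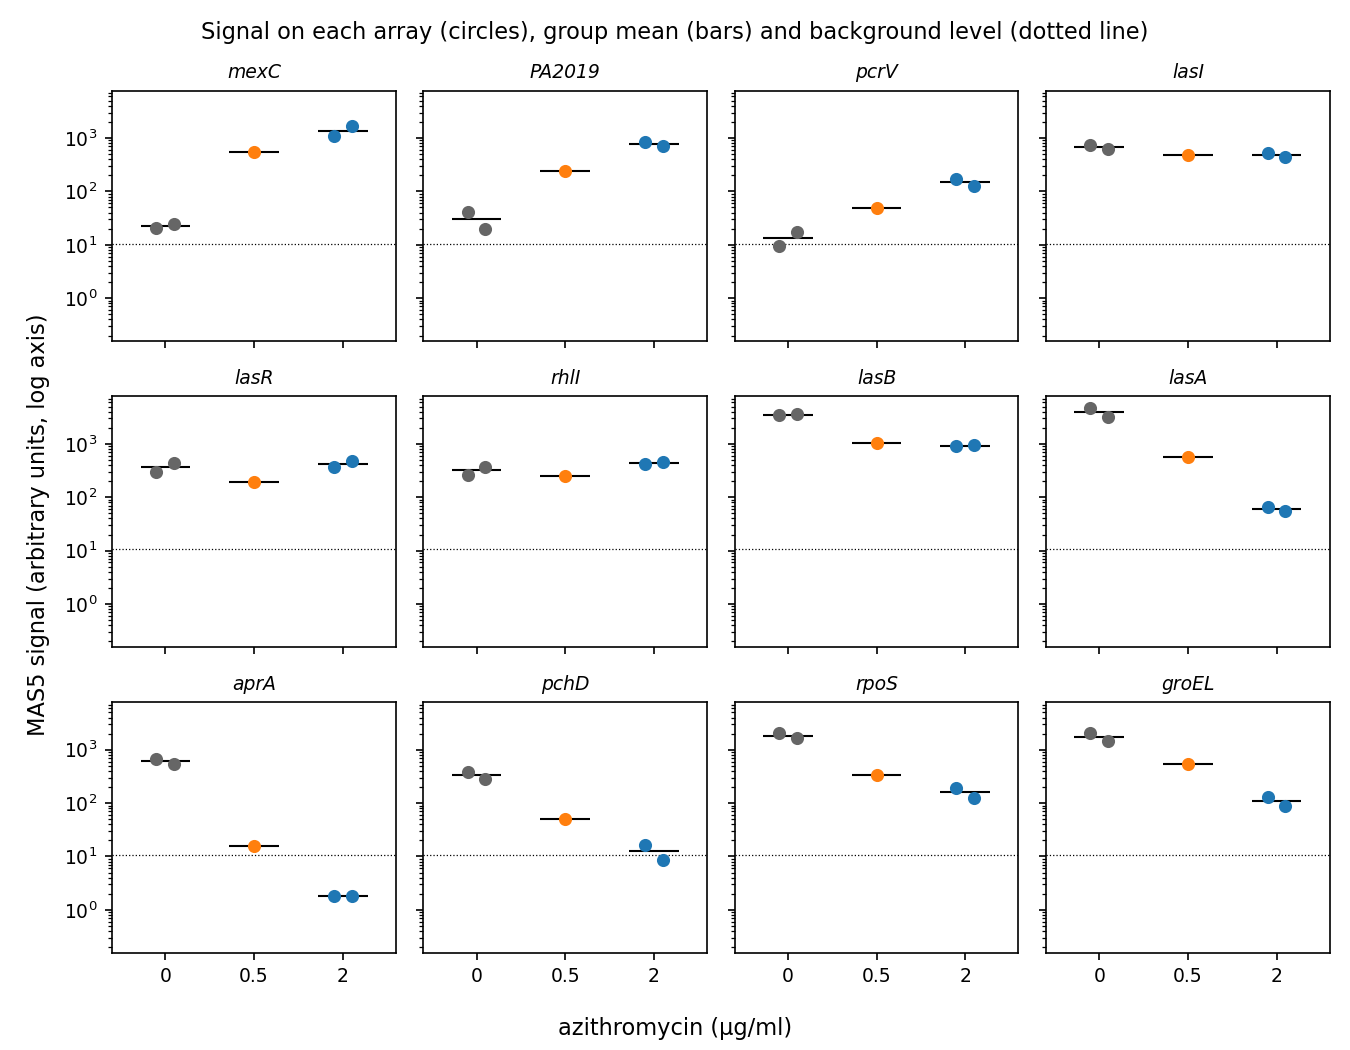
MAS5 signal on each array (circles, log axis, arbitrary units) by azithromycin concentration in µg/ml, with the group mean as a bar and the background level of 10.56 as a dotted line, for 12 genes. The signals of *mexC*, PA2019 and *pcrV* lay higher and those of *lasB*, *lasA*, *aprA*, *pchD*, *rpoS* and *groEL* lower with the drug, while those of *lasI*, *lasR* and *rhlI* did not pass the threshold.

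Methionine and S-adenosylmethionine are the precursors of the acyl-homoserine lactones. Of 9 genes for their synthesis 6 fell, and 7 adjusted over the list alone (median −0.84, camera adjusted p = 0.0405; adjusted p = 0.569 with an estimated correlation). S-adenosylmethionine synthetase, *metK*, fell 3-fold (103 ± 8.27 against 326 ± 15.9, adjusted p = 0.000728), *metF* fell with a log2 change of −1.12 ± 0.23, and *metH* with −1.34 ± 0.26. The call of this list was lost without untreated replicate 1 (adjusted p = 0.0779), without replicate 1 or 2 at 2 µg/ml (0.063 and 0.243), without the dimmest 25% of probe sets, and with the length trend removed (0.139), over a range of 0.0177 to 0.243. *metH* did not pass with the length trend removed (−0.41, adjusted p = 0.198; range 0.0003 to 0.198). Of 17 fatty acid synthesis genes, which supply the acyl chains, 8 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.252). *fabD* rose (1.52 ± 0.23), and *fabH2* fell (−1.59 ± 0.24).

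Genes for iron acquisition fell as 3 lists. All 11 genes for pyochelin, the weaker of the secreted iron chelators, were lower, also when adjusted over the list alone, with a median log2 change of −3.06 (camera adjusted p = 4.23e-07; adjusted p = 0.417 with an estimated correlation). *pchB* changed by −3.89 ± 0.24, *pchC* by −3.62 ± 0.25, *pchD* by −4.04 ± 0.29 and *pchA* by −3.46 ± 0.26. Of 21 genes for pyoverdine, the main iron chelator, 17 fell and 0 rose in limma at either adjustment, over all genes or adjusted over the list alone (median −1.60, camera adjusted p = 1.02e-06; adjusted p = 0.417 with an estimated correlation). They included the sigma factor gene *pvdS* (−2.48 ± 0.24) and the synthesis genes *pvdA* (−3.18 ± 0.26), *pvdH* (−3.24 ± 0.25) and *pvdL* (−2.72 ± 0.26), the last 2 with means under background with the drug. Of 7 genes for haem uptake and iron-starvation enzymes 6 fell, also when adjusted over the list alone (median −1.77, camera adjusted p = 0.00235; adjusted p = 0.468 with an estimated correlation), among them *sodM*, the manganese superoxide dismutase gene (−2.63 ± 0.23).

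Type III secretion, which injects toxins into host cells, was a list that rose. Of its 40 genes 23 rose and none fell, and 24 rose adjusted over the list alone (median 0.85, camera adjusted p = 1.51e-07; adjusted p = 0.417 with an estimated correlation). The needle tip gene *pcrV* had the largest rise, 2.87 ± 0.28, from a signal of 13.4 ± 5.23, near background, to 149 ± 32.3. The regulatory gene *exsD* rose by 2.16 ± 0.27, *exsB* by 2.19 ± 0.24 and the toxin gene *exoT* by 1.87 ± 0.24. Efflux pumps of the RND family and their regulators were the other, with 7 of 16 genes higher and 1 lower, also when adjusted over the list alone (median 0.52, camera adjusted p = 0.00579; adjusted p = 0.444 with an estimated correlation). With *mexC* and PA2019 rose *nfxB*, the repressor gene of the MexCD-OprJ operon (2.74 ± 0.28), and *mexR*, the repressor gene of MexAB-OprM (2.11 ± 0.24). PA2018 (*mexY*) rose 2.73-fold (56.6 ± 11.3 against 15.8 ± 6.65, adjusted p = 0.00312), while *mexB*, the pump subunit of MexAB-OprM, fell (−1.30 ± 0.23), though it did not pass with the length trend removed (adjusted p = 0.119, range 0.000822 to 0.119).

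Every chaperone and heat-shock protease gene measured, 12 of 12, fell with the drug, also when adjusted over the list alone (median −2.24, camera adjusted p = 1.47e-06; adjusted p = 0.417 with an estimated correlation). *groEL* fell from 1758 ± 392 to 111 ± 29.5, and the log2 change was −3.64 ± 0.27 for *hslU*, −2.96 ± 0.24 for *ibpA* and −2.23 ± 0.25 for *groES*. Of 11 genes for defence against oxidative stress 8 fell and 1 rose, also when adjusted over the list alone (median −1.57, camera adjusted p = 0.00614; adjusted p = 0.469 with an estimated correlation). The catalase gene *katA* fell with −3.35 ± 0.27 and the thioredoxin reductase gene *trxB2* with −2.50 ± 0.28, and the regulator gene *oxyR* rose (1.39 ± 0.24). Of 37 genes for R- and F-type pyocins, phage tail-like particles that kill related bacteria, 27 fell and 30 adjusted over the list alone (median −1.19, camera adjusted p = 8.38e-07; adjusted p = 0.444 with an estimated correlation). PA0633 changed by −1.81 ± 0.23 and PA0634 by −1.88 ± 0.29. Of 15 genes of the Pf prophage 5 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.152), with the coat protein gene *coaB* at −2.43 ± 0.27.

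In energy metabolism, 8 of 16 genes of the TCA cycle fell and none rose, also when adjusted over the list alone (median −1.22, camera adjusted p = 0.00811; adjusted p = 0.569 with an estimated correlation). The largest falls among those with the smallest p were in the succinyl-CoA synthetase genes *sucD* (−2.87 ± 0.23) and *sucC* (−2.74 ± 0.24) and in the aconitase genes *acnA* and *acnB* (−2.84 ± 0.27 and −2.82 ± 0.28). The list of ATP synthase and NADH dehydrogenase I held 11 genes that fell and 4 that rose of 22 (11 and 5 adjusted over the list alone) and did not pass (camera adjusted p = 0.0645, range 6.9e-05 to 0.104, with 6.9e-05 and 0.000641 without replicate 1 or 2 at 2 µg/ml). All 11 that fell were *nuo* genes, such as *nuoL* (−3.61 ± 0.25) and *nuoF* (−3.44 ± 0.24). The 4 that rose were *atpB* (2.22 ± 0.25), *atpI* (1.58 ± 0.24), *atpH* (0.94 ± 0.23) and *nuoA* (1.82 ± 0.23). Of 29 denitrification genes 10 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.224). The nitrite transporter gene *narK1* rose (2.63 ± 0.24) from a signal below background. The arginine fermentation genes *arcA*, *arcB* and *arcC* fell with −2.44 ± 0.30, −2.41 ± 0.32 and −2.50 ± 0.39, in a list of 9 with 5 lower, also when adjusted over the list alone (camera adjusted p = 0.211, range 0.032 to 0.267, with 0.032 without replicate 1 at 2 µg/ml).

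For the machinery that the drug acts on, 14 of 53 ribosomal protein genes rose and 10 fell (14 and 11 adjusted over the list alone). This split depended on the processing, and the number that fell moved more over the alternatives than the number that rose. The median was −0.07 and the mean 0.12, camera pointed up (adjusted p = 0.211), and the median turned to 0.16 under median centring. *rplI* rose by 2.12 ± 0.23 and *rpmA* by 2.05 ± 0.23. Of 10 genes of the translation and transcription core 5 fell and 2 rose, and adjusted over the list alone 6 fell (camera adjusted p = 0.224). *rpoB* and *rpoC* of RNA polymerase were lower (−2.08 ± 0.27 and −2.01 ± 0.30) and the initiation factor gene *infA* was higher (2.76 ± 0.32). The probe set of *tufA* cannot be told from its copy. Among 14 global regulators 4 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.778). The stationary-phase sigma factor gene *rpoS* had signals of 2041 and 1641 without the drug and of 195 and 125 with it (−3.48 ± 0.28). The main sigma factor gene *rpoD* fell by 1.86 on the log2 scale, and *spoT* and *relA*, for the alarmone ppGpp, changed by −1.56 ± 0.23 and −1.01 ± 0.24. The call of *relA* was lost with the length trend removed (−0.39, adjusted p = 0.198), without replicate 2 at 2 µg/ml (0.0524) and without untreated replicate 1 (0.0528), over a range of 0.00331 to 0.198.

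At the cell surface, 11 of 22 genes for the exopolysaccharides Pel and Psl fell and 1 rose, also when adjusted over the list alone (median −0.77, camera adjusted p = 0.00602; adjusted p = 0.417 with an estimated correlation). The members with the smallest p were all *psl* genes, *pslE* at −3.17 ± 0.25, *pslH* at −2.20 ± 0.24, and *pslC* and *pslD* each at −2.22, and the gene that rose was *pslA* (1.55 ± 0.29). Of 47 genes of the type VI secretion clusters 19 fell and 4 rose, also when adjusted over the list alone (median −0.49, camera adjusted p = 0.0251; adjusted p = 0.569 with an estimated correlation). PA2366 and PA2367 of the third cluster changed most (−4.19 ± 0.24 and −3.86 ± 0.23), and the list did not pass with the length trend removed (adjusted p = 0.139, range 0.0127 to 0.139). Flagellar and chemotaxis genes went both ways, with 12 of 48 higher and 15 lower (12 and 16 adjusted over the list alone; camera adjusted p = 0.906). The hook-associated *flgK* fell (−2.94 ± 0.25), and the sigma factor gene *fliA* rose (1.73 ± 0.26). The list's median of −0.21 became 0.03 under median centring.

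The remaining lists did not pass for 2 µg/ml. Type IV pili had 12 lower and 4 higher of 30 (13 and 5 adjusted over the list alone; camera adjusted p = 0.252), with *pilQ* at −2.54 ± 0.23. The type II secretion genes had 4 lower and 1 higher of 11, also when adjusted over the list alone (camera adjusted p = 0.0929), with *xcpT* at −2.30 ± 0.25 and *xcpP* at 1.55 ± 0.24. Genes for PhoPQ, PmrAB and lipid A modification had 8 lower and 1 higher of 16 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0929), with *arnA* at −1.64 ± 0.23 and *phoP* at 1.30 ± 0.23. The alginate list had 3 lower and 2 higher of 16, also when adjusted over the list alone (camera adjusted p = 0.842). *algA* and *algF* were lower (−1.37 ± 0.26 and −1.57 ± 0.30), and the sigma factor gene *algU* was higher (1.13 ± 0.26), but not past the threshold without untreated replicate 1 (adjusted p = 0.0553, range 0.00228 to 0.0553). The O antigen cluster had 5 lower and 3 higher of 16, also when adjusted over the list alone. Its median of −0.34 and its mean of −0.21 opposed camera's upward direction (adjusted p = 0.965). In all, 13 of the 29 lists passed with the preset correlation, 11 lower and 2 higher, and 0 passed with camera's estimated correlation, where the smallest adjusted p was 0.417. With fry, which tests whether a list's genes move one way on balance, 17 passed.

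**Figure D2:**
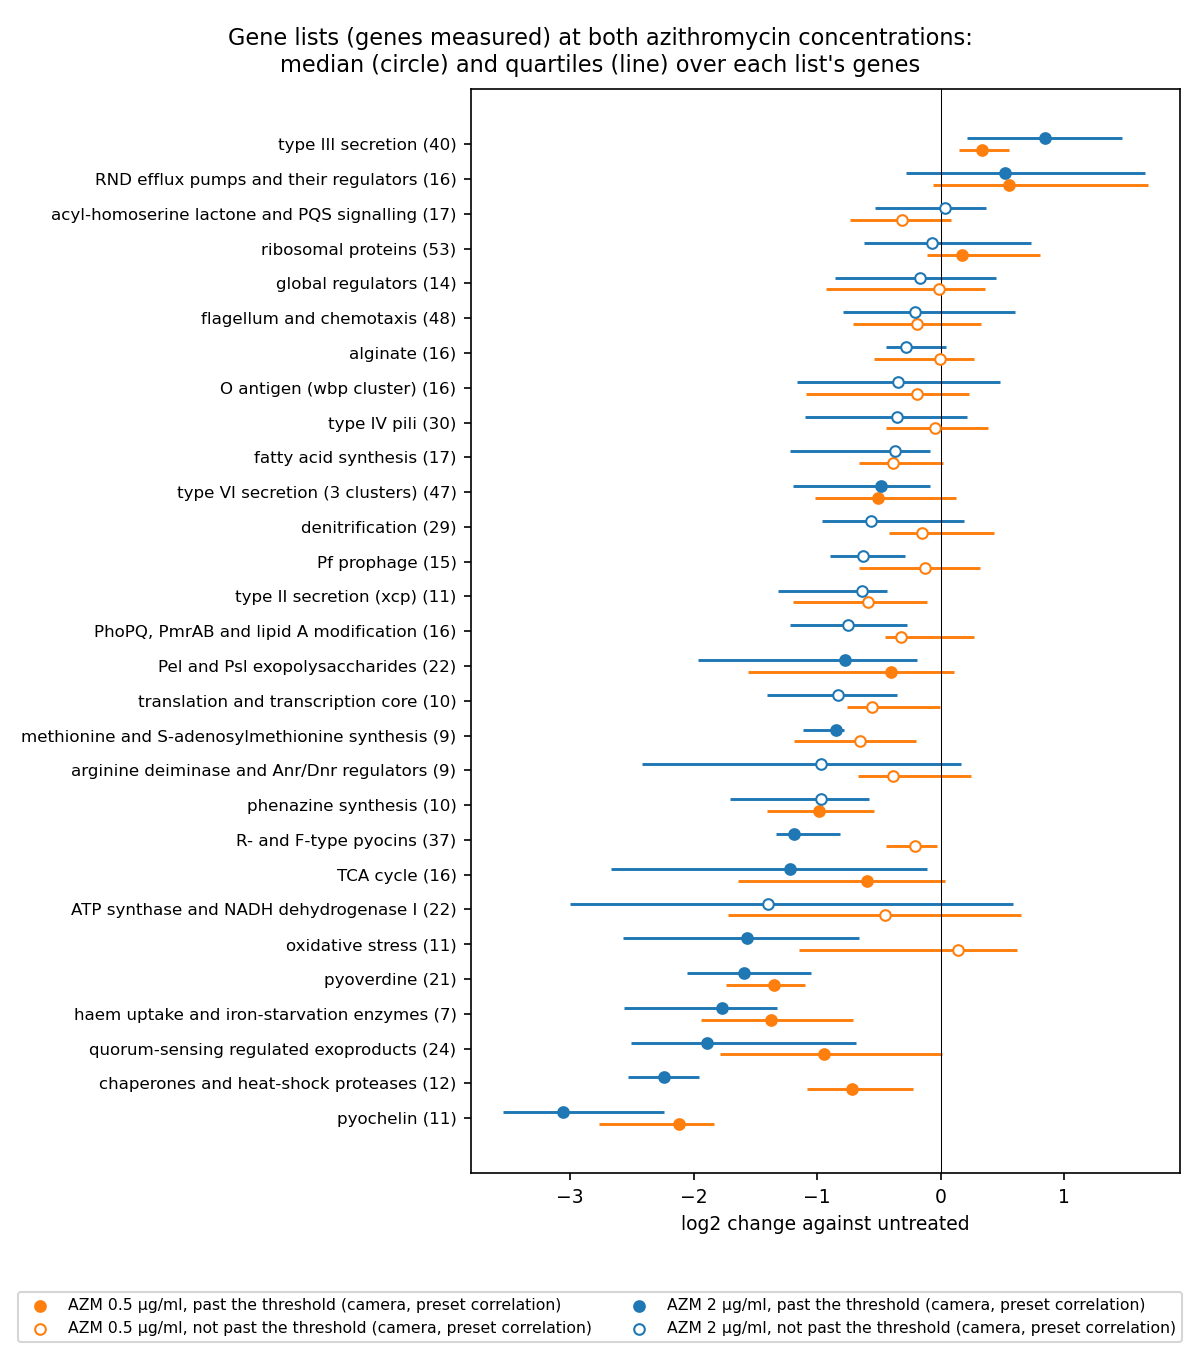
Median (circle) and quartiles (line) of the log2 change against untreated over the genes of each of the 29 lists, at 0.5 µg/ml (orange) and 2 µg/ml (blue) azithromycin, with the number of genes measured in brackets. Filled circles passed camera with the preset correlation, 13 lists at 2 µg/ml and 12 at 0.5 µg/ml, and the pyochelin genes had the lowest median, −3.06.

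The second comparison asked what the lower concentration, 0.5 µg/ml, does. Of the pump genes, *mexC* was 18.3-fold higher (557 on the single array against 22.7 ± 2.83, SD, n = 2; log2 change 4.20 ± 0.34 SE, adjusted p = 0.000619), and PA2019 6.76-fold higher (adjusted p = 0.00167). *aprA* was 25.6-fold lower (15.6 against 604 ± 84.6, adjusted p = 0.00039). PA2018 was not distinguishable from untreated (−0.05 ± 0.34, adjusted p = 0.945). The magnesium transporter gene *mgtA* was 17.1-fold higher (1466 against 78.7 ± 12.4), and its neighbour PA4822 10.8-fold. The *ant* genes for anthranilate breakdown fell, *antA* with −3.26 ± 0.32 to a signal of 4.8, under background, and *antB* with −3.22 ± 0.34, as did *prpB* of propionate breakdown (−3.30 ± 0.29), *pvdA* (−3.19 ± 0.31) and *rmf* (−3.17 ± 0.32).

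At this concentration 1065 genes (19.2%) passed the threshold, 452 higher and 613 lower. The split depended on the scaling. Under median centring slightly more genes were higher than lower, unlike under quantile normalization, and the median log2 change of all genes went from −0.07 to 0.03. The test assumes that the single array varies like the other groups. Without untreated replicate 1 the count was 572 and without untreated replicate 2 it was 652, with 1 residual degree of freedom. The array lay outside the range of both untreated arrays for 79.6% of genes, where chance gives 66.7%. The other genes with the largest rises were PA2712 (4.02 ± 0.30), PA4574 (3.79 ± 0.29), PA4963 (3.72 ± 0.30), and PA1343 (3.68 ± 0.33), followed by PA4059 (3.60 ± 0.34), PA3277 (3.45 ± 0.34), PA5357 (3.39 ± 0.31), *trpG* (3.38 ± 0.31) and PA4635 (3.35 ± 0.34). Those with the largest falls were PA4139 (−3.64 ± 0.36), PA2171 (−3.55 ± 0.31), PA0049 (−3.43 ± 0.35), PA2366 (−3.34 ± 0.29), PA5461 (−3.33 ± 0.40) and PA4377 (−3.19 ± 0.35).

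Of the signalling genes, *lasI* (−0.48 ± 0.30, adjusted p = 0.319), *lasR* (−0.91 ± 0.34, adjusted p = 0.0965) and *rhlI* (−0.31 ± 0.31, adjusted p = 0.549) did not pass, nor did *rhlR* (0.05 ± 0.32, adjusted p = 0.93), *pqsA* (0.59 ± 0.28, adjusted p = 0.196) and *mvfR* (0.40 ± 0.28, adjusted p = 0.384). *lasB* fell 3.43-fold (adjusted p = 0.00363) and *metK* 2.9-fold (adjusted p = 0.00674), and *rhlA* did not pass (−0.32 ± 0.28, adjusted p = 0.493). Of the exoproduct list 11 genes fell and 0 rose over all genes with limma, and 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000568; adjusted p = 0.535 with an estimated correlation).

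Iron acquisition fell here as well, with 10 of 11 pyochelin genes lower (11 adjusted over the list alone; median −2.11, camera adjusted p = 2.69e-08; adjusted p = 0.535 with an estimated correlation). Of the pyoverdine genes 16 of 21 fell, also when adjusted over the list alone (median −1.35, camera adjusted p = 5.48e-08; adjusted p = 0.535 with an estimated correlation). Of the haem and iron-starvation list 4 of 7 fell (5 adjusted over the list alone; camera adjusted p = 0.00323; adjusted p = 0.535 with an estimated correlation). The efflux list had 7 of 16 genes higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00369; adjusted p = 0.535 with an estimated correlation), with *nfxB* at 1.95. Of 10 phenazine genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.535 with an estimated correlation).

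Of 53 ribosomal protein genes 9 rose and 0 fell in limma, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.00628; adjusted p = 0.535 with an estimated correlation). *rpmA* rose by 2.28 and *rplU* by 2.07, and the list did not pass under quantile normalization (adjusted p = 0.143) or with the length trend removed (adjusted p = 0.0965; range 0.00423 to 0.143). In the type III secretion list 2 genes rose and 1 fell of 40, and none adjusted over the list alone (median 0.33, camera adjusted p = 0.00876; adjusted p = 0.535 with an estimated correlation). Further lists that passed were Pel and Psl (9 of 22 lower and 1 higher; 10 and 1 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.535 with an estimated correlation). Type VI secretion passed too (11 of 47 lower and 1 higher, also when adjusted over the list alone; camera adjusted p = 0.0169; adjusted p = 0.692 with an estimated correlation). The TCA cycle list had 7 of 16 genes lower, also when adjusted over the list alone (camera adjusted p = 0.0295; adjusted p = 0.762 with an estimated correlation). The chaperone list had 3 of 12 lower (4 adjusted over the list alone; camera adjusted p = 0.0339; adjusted p = 0.545 with an estimated correlation). With the length trend removed, the adjusted p was 0.0828 for Pel and Psl, 0.106 for type VI secretion, 0.0884 for the TCA cycle and 0.102 for the chaperones. Over the alternatives it ranged from 0.00543 to 0.0828, 0.00971 to 0.106, 0.00845 to 0.102 and 0.0128 to 0.102. The calls of type VI secretion, the TCA cycle and the chaperones were also lost without untreated replicate 1, which sets 1 array against 1. That of the chaperones was lost without an array at 2 µg/ml. For this comparison, leaving out replicate 1 or replicate 2 at 2 µg/ml gives the same result, so this is 1 loss. With the pseudocount at the 1st percentile the TCA cycle and the chaperones did not pass either (0.0592 each). Of 37 pyocin genes 0 passed in either direction with limma, also when adjusted over the list alone (median −0.20, camera adjusted p = 0.41). The other 16 lists did not pass, 12 of the 29 passed with the preset correlation, and 0 did with camera's estimated correlation, while fry called 2.

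The 2 concentrations gave similar changes. Of the 452 genes higher at 0.5 µg/ml, 432 (95.6%) were also among the 957 higher at 2 µg/ml, where independent lists would share 78. Of the 613 lower genes, 582 (94.9%) were also among the 1353, where independent lists would share 150, and 2 genes were called in opposite directions. Across genes the log2 changes correlated with r = 0.897 (Spearman's rho 0.86). In 100 simulations of unchanged groups against the same controls the mean r was 0.408, and at most 0 higher and 1 lower genes were shared calls of limma. Where no gene is changed almost none is called, so the simulated shared calls cannot show how much of the observed overlap comes from the controls. The covariance was 0.868 against 0.0361 in the simulations, and the difference of 0.832 is more than the spread between arrays of a group gives. The simulated noise had only this spread, which may be technical. A departure common to both untreated arrays would therefore remain in the difference, which cannot be told from a shared response to the drug. The untreated arrays could not be split, since each part would hold 1 array, so part of the excess of shared calls over independent lists may come from the shared controls. Among the genes called at 2 µg/ml, 97.4% had the same sign at 0.5 µg/ml, 84.1% a smaller change, and the median ratio of the changes was 0.708. These genes were chosen by their change at 2 µg/ml, which by itself favours a smaller change at 0.5 µg/ml. The sign and ratio also share the untreated arrays, so they do not measure an effect of the concentration.

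**Figure D3:**
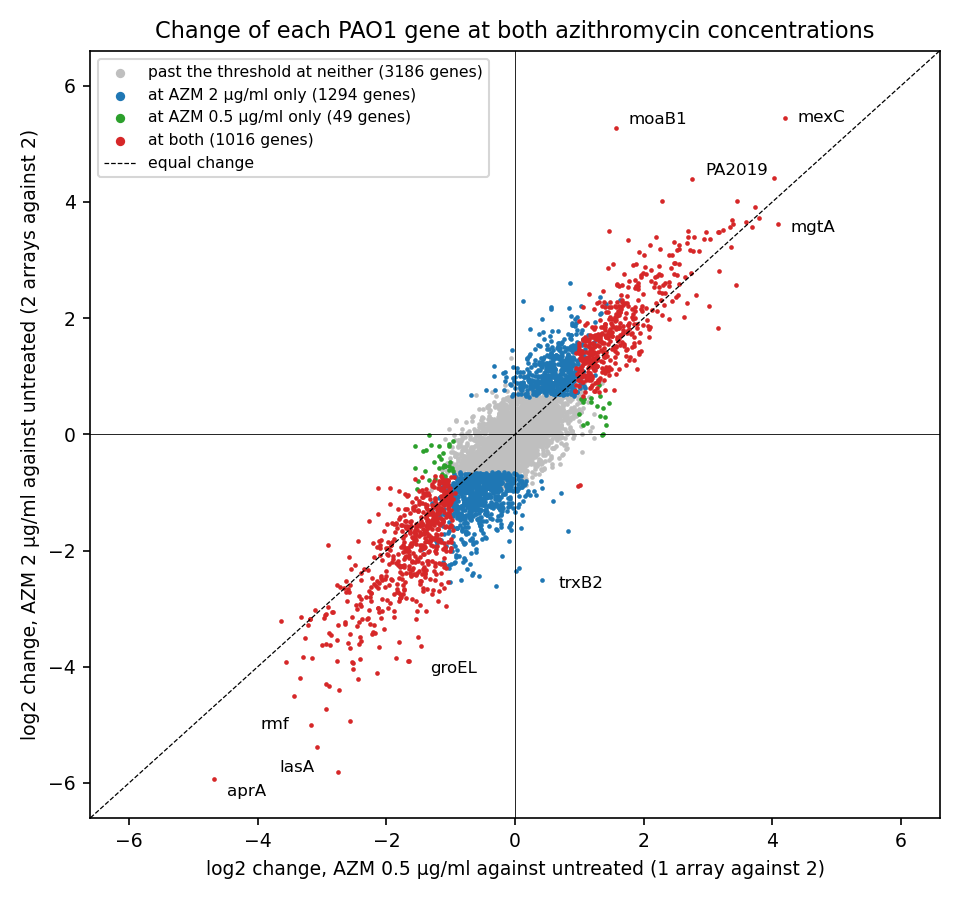
Log2 change of each of 5545 genes against untreated at 0.5 µg/ml (horizontal axis, 1 array) and 2 µg/ml azithromycin (vertical axis, 2 arrays), coloured by the comparison in which it passed the threshold, with a dashed line of equal change. 1016 genes passed at both concentrations, and r across genes was 0.897.

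The third comparison tested the 2 concentrations against each other. *moaB1* was the only gene higher at 2 than at 0.5 µg/ml past the threshold, by 13.1-fold. Its signal was 643 ± 22.6 (SD, n = 2) against 41.4 on 1 array (limma adjusted p = 0.0038, at most 0.106 over the alternatives). Lower at 2 µg/ml were 14 genes, among them *lasA* (8.32-fold, 60.9 ± 7.78 against 565, adjusted p = 0.0164), *trxB2* (7.57-fold, 32.5 ± 11 against 294, adjusted p = 0.0164) and the catalase gene *katB* (5.62-fold). Others were *groEL* (4.77-fold, adjusted p = 0.0401), the protease subunit gene *hslU* (4.5-fold, adjusted p = 0.0401) and *nirL* of haem d1 synthesis (4.1 against 53.1, the former under background). The rest were PA3237, PA2433, PA3416, PA3417, PA0586 and PA3460, and PA3287 and PA0848. The means of PA3237, PA3416 and PA3460 at 2 µg/ml were also under background. Fits without 1 of the arrays at 2 µg/ml set 1 array against 1, with the spread taken from the untreated arrays alone. Their counts therefore do not test this count of 15. Without either untreated array *moaB1* alone still passed. With the pseudocount at the 1st percentile the count was 0 in limma. In the main test 700 genes had an unadjusted p under 0.05.

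The largest differences upward that missed the threshold were those of *exsC* (2.17 ± 0.56, adjusted p = 0.161), PA1541 (2.03 ± 0.37), and PA1415 (1.75 ± 0.42). Next were PA3386 (1.72 ± 0.28, adjusted p = 0.0594), PA2019 (1.64 ± 0.37, adjusted p = 0.13), PA0839 (1.64 ± 0.35), *exsD* (1.60 ± 0.33), *nuoA* (1.59 ± 0.29), PA0128 (1.58 ± 0.33), PA0789 (1.56 ± 0.30) and PA2018 (56.6 ± 11.3 against 14.6, adjusted p = 0.136). Some fits without 1 of the arrays at 2 µg/ml called these genes. Such fits set 1 array against 1, with the spread taken from the untreated arrays alone, so they carry no weight here. PA3386, PA1541, *exsD*, *nuoA* and PA0789 also passed in other alternatives. For PA3386 the removal of the length trend was among them (limma adjusted p = 0.0375). The difference was −0.02 ± 0.30 for *lasI*, 1.13 ± 0.34 for *lasR* (adjusted p = 0.214), 0.80 ± 0.31 for *rhlI* and 0.67 ± 0.32 for *rhlR*. It was 0.63 ± 0.28 for *pqsA*, −0.03 ± 0.28 for *mvfR*, −0.16 ± 0.28 for *lasB*, −0.52 ± 0.28 for *rhlA* and −0.05 ± 0.28 for *metK*, and the adjusted p of each was above the threshold.

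As lists, the pyocin genes were lower at the higher concentration, with a median difference of −0.95 (camera adjusted p = 2.99e-15; adjusted p = 0.359 with an estimated correlation). Of the 37, 0 passed over all genes in limma and 26 were lower adjusted over the list alone. The chaperones had a median difference of −1.65, with 2 of 12 lower and 12 adjusted over the list alone (camera adjusted p = 1.05e-14; adjusted p = 0.359 with an estimated correlation). The oxidative stress list had 3 of 11 lower and 5 adjusted over the list alone (median −0.69, camera adjusted p = 7.36e-06; adjusted p = 0.382 with an estimated correlation). The exoproduct list had 1 of 24 lower and 12 adjusted over the list alone (median −0.73, camera adjusted p = 1.68e-05; adjusted p = 0.359 with an estimated correlation). The ATP synthase and NADH dehydrogenase list had 0 over all genes in limma, and 12 lower and 2 higher adjusted over the list alone (camera adjusted p = 2.79e-05; adjusted p = 0.382 with an estimated correlation). Type III secretion was higher at 2 µg/ml, with a median difference of 0.67 and 12 of 40 genes higher adjusted over the list alone, though 0 over all genes in limma (camera adjusted p = 7.9e-12; adjusted p = 0.359 with an estimated correlation). The signalling list was higher as well (median 0.20, camera adjusted p = 0.0155; adjusted p = 0.382 with an estimated correlation). None of its genes passed in limma, adjusted over the list alone included, and its call was lost under quantile normalization (adjusted p = 0.0629, range 0.0119 to 0.0629). Lists with smaller differences that passed were pyochelin (median −0.60, camera adjusted p = 0.000313; adjusted p = 0.382 with an estimated correlation; 3 of 11 lower adjusted over the list alone), the TCA cycle (−0.38, 0.00931, range 0.000359 to 0.125, with 0.125 without replicate 2 at 2 µg/ml; adjusted p = 0.574 with an estimated correlation), PhoPQ and PmrAB (−0.31, 0.00931; adjusted p = 0.382 with an estimated correlation) and denitrification (−0.34, 0.0142, range 0.00701 to 0.077, lost without the dimmest 25% of probe sets; adjusted p = 0.462 with an estimated correlation). The others were arginine fermentation (−0.59, 0.0165, range 0.000286 to 0.0519, lost with the pseudocount at the 1st percentile; adjusted p = 0.382 with an estimated correlation), type IV pili (−0.30, 0.0209, range 0.0106 to 0.0563, with 0.0563 without replicate 1 at 2 µg/ml; adjusted p = 0.48 with an estimated correlation) and the Pf prophage (−0.48, just past at 0.04998; adjusted p = 0.57 with an estimated correlation). So close to the threshold, the Pf prophage call depended on the alternative. Its camera adjusted p was 0.0313 with the length trend removed and reached 0.163 in another alternative. Ribosomal proteins (adjusted p = 0.0542, range 0.0191 to 0.186), O antigen (0.0544, range 0.0168 to 0.456) and haem uptake (0.0644, range 0.0117 to 0.139) missed the threshold but passed in 6, 4 and 2 of 14 alternatives. These counts, and the ranges given for the lists above, include fits without 1 of the arrays at 2 µg/ml. Those fits set 1 array against 1, so a pass or a loss there carries no weight. The calls of the TCA cycle and of type IV pili were lost in such a fit alone. Altogether 14 lists passed, 12 lower and 2 higher, and 0 with camera's estimated correlation or with fry.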

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

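The tests of kept calls, coding length, growth stage, the set of arrays, the single array, probe set brightness and chance assignment of genes were chosen after the results were seen, while the 2 scalings and the test of all but the control probe sets were planned. Some probe sets outside the tested genes passed the threshold when all but the control probe sets were tested together. Of 21 probe sets for tRNA or rRNA, 7 were higher at 2 µg/ml than untreated and 0 lower in limma (10 at an unadjusted p under 0.05), and of 199 intergenic probe sets 26 were higher and 8 lower. In the same test 936 of 5545 PAO1 genes were higher and 1322 lower, a larger share higher than among the intergenic probe sets. Of 117 probe sets for other strains or other sequences, 0 passed in limma and 1 had an unadjusted p under 0.05. The 7 were all tRNA probe sets, such as that for asparagine (308 against 88.5), and those for 16S, 23S and 5S rRNA had changes of −0.68, −0.67 and −0.42 that did not pass.

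The first pattern weighed was the breadth of the response, 2310 of 5545 genes at 2 µg/ml. Scaling of whole arrays as the whole cause is argued against by the calls kept in the same direction, 1960 of 2310 under median centring and 2016 under quantile normalization, although the split of higher and lower genes depends on the scaling. A trend with coding length as the whole cause is argued against by the 2215 genes that passed once it was removed, although the trend may carry part of the fall of long genes. An earlier growth stage of treated cells stays open: *rpoS* and *rmf* fell, but the ribosomal protein list had a median of −0.0708, with an upper quartile of 0.73. Culture density at collection is not in the labels.

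The second pattern was the pyocin list, lower at 2 than at 0.5 µg/ml. A departure of the second set of arrays is argued against by the first array at 2 µg/ml, whose median difference was −0.86, beside −0.95 for the second. Whether the single array at 0.5 µg/ml was unusual stays open. It lay outside the range of the other arrays in 4 of 37 members, where an array standing apart was predicted to do so in most. An array that departed toward the untreated level would stay within that range, so the count cannot decide. No second array at that concentration exists to compare. A response to the drug concentration is a further explanation that stays open.

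The third pattern was that exoproduct genes fell and signalling genes on balance did not. Too dim signalling probe sets are argued against, since 16 of 17 had an untreated mean above 4 times the background. In a permutation test that reassigned the genes between the lists, a difference of medians of −1.92 or more in size had p = 3e-04, though genes of a list are not independent. The difference may be biological, with regulation beyond the transcripts of the signalling genes as a candidate explanation, but it was found and tested on the same data and protein or signal levels were not measured.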

How the results depend on the processing

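Removal of the coding length trend was chosen after the data were seen. Over the named genes, 5682 of 5969 alternative values kept their call, 154 lost one, 133 gained one and 0 reversed, and every alternative ran. Most of these genes were named for large changes or small p, and values never called count as kept. Of all genes called at 2 µg/ml, 84.8% passed again under median centring and 85.6% with the pseudocount at the 1st percentile. With that pseudocount 62.5% passed again at 0.5 µg/ml. With the length trend removed, 11 genes called at 2 µg/ml and 1 at 0.5 µg/ml changed sign. Genes past the threshold at 0.5 µg/ml against untreated numbered 688 with the pseudocount at the 1st percentile, and 572 (without untreated replicate 1) to 1220 (without replicate 1 at 2 µg/ml) with 1 array left out. Between the concentrations, where 15 genes passed, there were 0 with the pseudocount at the 1st percentile, 25 at the 25th, 9 under quantile normalization, 44 without the dimmest 25% of probe sets, 6 with all probe sets but the controls, 26 with an intensity trend, and 1 (without untreated replicate 1) to 122 (without replicate 1 at 2 µg/ml). The correlation between the concentrations was 0.869 with the pseudocount at the 1st percentile and 0.866 to 0.907 with 1 array left out. With camera's estimated correlation 0, 0 and 0 lists passed at 2 µg/ml, at 0.5 µg/ml and between them, where the preset correlation gave 13, 12 and 14. With the length trend removed 7 lists passed at 0.5 µg/ml. The cause of these moves was not tested. At 2 µg/ml the count stayed between 1650 and 2314 apart from the block, and fitting without the 0.5 µg/ml array left it at 2310 by construction. A block term for the set of arrays gave 2848, 1471 and 16 genes. The labels give no number that pairs arrays, and the pairing check gave r = 0.346 between the replicate differences of the groups.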

Other observations

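Several sets of neighbouring genes moved together at 2 µg/ml, most without a member in the fixed lists (*chiC*, *rpmA*, *rplU* and PA5471 are members). The 6 genes from *chiC* to *ambB*, which include genes for the toxin L-2-amino-4-methoxy-trans-3-butenoic acid, had a median log2 change of −3.06, the propionate genes from *prpD* to PA0797 one of −2.75, and the periplasmic nitrate reductase genes from *napC* to *napF* one of −2.54. The tight adherence genes from *tadG* to *rcpA* had a median of −1.98, the malonate genes from *mdcA* to PA0214 one of −1.80, and the cell division and cell wall genes from *ftsZ* to *murD* one of −1.30. Neighbours that rose included PA4822 to PA4826 with *mgtA*, with a median of 2.57 at 2 µg/ml and 3.01 at 0.5 µg/ml, PA4564 to PA4568 with *rpmA* and *rplU* (1.86 and 2.07), and PA5470 to PA5474 (1.74 and 1.82), which hold PA5471, known to respond to drugs that act on the ribosome.

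The test of runs was written before its result was seen. If calls were scattered by chance along the chromosome, few would fall in runs of 5 or more neighbours that passed in 1 direction. There were 330 genes in 49 such runs, 8 higher and 41 lower, where 1000 shuffled orders gave a median of 21 and at most 61. Chance order is argued against, and shared transcripts are a candidate explanation that may account for the runs. Transcript ends were not measured.

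The called share was 55.5% among the brighter 50% of genes and 27.8% among the dimmer, so the calls at 2 µg/ml did not come mainly from dim probe sets. A hypothesis drawn from these data is that cells with the drug may have entered stationary phase later or less fully, since *rpoS*, *rmf* and *katA* were lower. These genes were picked after their values were seen, and other genes do not point one way. *rpoB*, *rpoC*, *rpoD* and the genes from *ftsZ* to *murD* (median −1.30) were lower too, and the quorum-sensing regulated *hcnA* and *hcnB* rose. The ribosomal protein median of −0.0708 left the hypothesis open, and a series of samples over growth, with cell density, would test it.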
